A study of Homo sapiens with 8 samples.

How the data were processed

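MicroRNAs (miRNAs, short RNAs that repress matching messenger RNAs) were measured by small RNA sequencing in HCT116 cells, a human colorectal cancer cell line. Per the labels' protocols, spheroids were grown from these cells in serum-free medium in low-attachment flasks, stained with an antibody against CD44v6, and sorted by flow cytometry into CD44v6-positive and CD44v6-negative cells. CD44v6 is a splice form of the hyaluronan receptor CD44. Dead cells were removed with propidium iodide, total RNA was extracted, and libraries were made with an Illumina small RNA kit and size-selected on a gel.

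Raw read counts per mature miRNA were deposited by the authors as 1 table of whole numbers. The authors also deposited the same counts as a normalized signal. In each column that signal was the raw count divided by 1 size factor, of 3.09 and 3.58 for CD44v6-negative samples 1 and 2, and of 0.576 and 0.156 for CD44v6-positive samples 1 and 2. Those factors equalled the DESeq2 median-of-ratios factors recomputed from the raw counts. The normalized table was used for this check only. Per the submitters' processing notes the tools were CASAVA 1.8.2, cutadapt 1.10, Bowtie 0.12.9 and DESeq2, with genome build GRCh38, and their roles, the miRNA annotation, the mismatch setting and the treatment of multiply mapped reads are not given in the sources used here. Reads of miRNAs that share sequence, such as members of the let-7 family, could therefore not be assigned with certainty, and 8 of the 2026 table entries join mature names of identical sequence.

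The labels list 8 sequencing entries, which carry 4 combined identities with 2 entries each. Per the file headers each column holds 1 combined identity, so the entries of 1 identity were counted as 1 sample and n was 2 per group, although the series text counts 4 per group. Tests that need the 8 entries apart were not analysed here. The labels do not say that samples 1 and 2 of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

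The comparison was CD44v6-positive against CD44v6-negative cells. The test was edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest with default settings, which in this version are the legacy ones) on the raw counts, after TMM scaling and filterByExpr with a minimum count of 10 and a minimum total count of 15. A miRNA passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Log2 fold changes are positive minus negative, and the standard error is the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM (reads of a miRNA per 1000000 reads) scaled by TMM, as mean ± SD of 2 samples. Of the 2026 entries, 1510 had a read in any sample and 570 were tested.

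The raw counts summed to 7880631 and 4592278 reads in CD44v6-negative samples 1 and 2, and to 919802 and 154481 reads in CD44v6-positive samples 1 and 2, a 51.0-fold span from deepest to shallowest. A count of 3 reads, the upper limit that a count of 0 allows, was 0.381, 0.653, 3.26 and 19.4 CPM in these samples before TMM scaling. Such limits cover counting error only, since reads amplified by PCR are not independent molecules.

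Before the data were examined, 27 lists of miRNAs were fixed, and so were the test, the alternatives and the rule for naming miRNAs. The lists were the let-7 family with miR-98, the miR-200 family, miR-34 with miR-449, the miR-17-92, miR-106b-25 and miR-106a-363 clusters, the pluripotency clusters of miR-302 and of miR-371 to miR-373, miR-15 with miR-16, miR-424 with miR-503, miR-23 with miR-24 and miR-27, miR-29, miR-30, miR-181, miR-221 with miR-222, miR-183 with miR-96 and miR-182, miR-192 with miR-194 and miR-215, miRNAs often reported raised in colorectal tumours, miR-99 with miR-100 and miR-125, HOX-cluster miRNAs, NF-kB-responsive miRNAs, the hypoxia-induced miR-210, the imprinted cluster at DLK1-DIO3, the primate cluster on chromosome 19, markers of blood and endothelium, of stroma and muscle, and of neural cells and liver, and miRBase entries thought to derive from other noncoding RNA. Lists with 3 or more tested members were tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the lists, and again with camera at an estimated correlation and with fry. The rule named the 12 largest changes in each direction if at least 5 miRNAs passed, and otherwise the 10 miRNAs with the smallest p, given as values that did not pass. It added the 5 most abundant miRNAs, up to 4 of the most abundant members of each list described, and 13 miRNAs chosen for their link to CD44 or to colorectal cancer. Which 9 lists were described with members was decided after the values were seen.

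Hairpin positions came from GENCODE release 29 on GRCh38, in which 2024 of the 2026 names (99.9%) matched a hairpin gene by name. GC content was taken from the 5′ or 3′ part of the hairpin that carries the arm, or from the whole hairpin where the name has no arm, averaged over copies. It is a stand-in for the mature sequence, which was not used here, and 569 of the 570 tested miRNAs had a value.

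The script was tested on simulated data before use. In 10 simulated tables of 570 unchanged miRNAs at the depths of these 4 samples, at most 2 miRNAs passed. In 10 tables with 200 changed miRNAs, the test called 29.6% of 4-fold and 87.5% of 16-fold changes, and 3.31% of its calls were unchanged miRNAs. A list shifted 4-fold was called in 10 of 10 tables. The tables with 200 changed miRNAs gave a mean of 113.1 calls, whereas the test of the real samples gave 0. These rates therefore describe the simulated tables only and may not apply to the real samples.

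Alternatives fixed in advance were RLE, upper quartile and total count scaling, leaving the most abundant miRNA out of the library sizes, no filter, a filter of 10 CPM in 2 samples, DESeq2 1.42.0, limma-voom, robust and legacy fits, the replicate number as a block, a 2-fold minimum, and leaving out each sample in turn. A loess correction for GC content (span 0.75), thinning of all samples to the depth of the shallowest (20 draws), the newer non-legacy fit and DESeq2 with its independent filtering tuned to 0.05 were chosen after seeing the data. Figures were drawn with matplotlib.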

Results

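Small RNA reads were counted per mature miRNA in 4 samples of HCT116 spheroid cells, 2 sorted as CD44v6-positive and 2 as CD44v6-negative. CD44v6 is used as a surface marker of stem-like colorectal cancer cells, and the series set out to find miRNAs associated with such cells. The CD44v6-negative samples held 7880631 and 4592278 reads in 1256 and 1351 detected miRNAs. The CD44v6-positive samples held 919802 and 154481 reads in 863 and 627 detected miRNAs, so depth differed between the groups. Across the 570 tested miRNAs, which are not independent replicates, log2 CPM of the CD44v6-negative samples correlated at a Pearson r of 0.959, that of the CD44v6-positive samples at 0.888, and pairs across the groups at 0.785 to 0.903.

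miR-1246 stood far higher in CD44v6-positive cells, at 2029 ± 1029 CPM against 68.9 ± 17.8 CPM in CD44v6-negative cells (SD, n = 2), a log2 fold change of 4.88 ± 0.65 (SE). miR-3605-3p was at 196.5 ± 16.9 against 10.8 ± 0.380 CPM, a log2 fold change of 4.18 ± 0.59. Other miRNAs lay lower in CD44v6-positive cells. The passenger strand miR-21-3p was at 1680 ± 32.2 against 11841 ± 692 CPM, and miR-19a-3p and miR-18a-5p, both from the miR-17-92 cluster, were at 108 ± 19.9 against 1136 ± 200 CPM and at 134 ± 42.3 against 1002 ± 64.8 CPM. None of the 570 tested miRNAs passed an adjusted p under 0.05 in edgeR's quasi-likelihood test, so these are values that did not pass.

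The other miRNAs among the 10 with the smallest p went both ways. miR-31-3p had a log2 fold change of -4.21 ± 0.77, miR-29b-3p of -3.63 ± 0.68 and miR-374a-5p, from the noncoding gene FTX, of -3.18 ± 0.60. The value of miR-31-3p rests on 63 and 3 reads in CD44v6-positive samples 1 and 2, and with 1 sample left out it ran from -5.87 to -3.41. miR-423-5p was at 18125 ± 14291 against 1361 ± 7.77 CPM, a log2 fold change of 3.73 ± 0.71. miR-125b-2-3p had a log2 fold change of 6.27 ± 1.20, from 4 reads in each CD44v6-negative sample against 15 and 22 reads in the CD44v6-positive samples. At their unequal depths the latter were 16.2 and 115 CPM, so the 2 CD44v6-positive samples differed widely. With 1 sample left out the log2 fold change of miR-125b-2-3p ran from 4.61 to 7.08. In each of the 10, both CD44v6-positive samples lay on one side of both CD44v6-negative samples, which picking by small p favours. Each had an edgeR adjusted p of 0.0787.

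**Figure D1:**
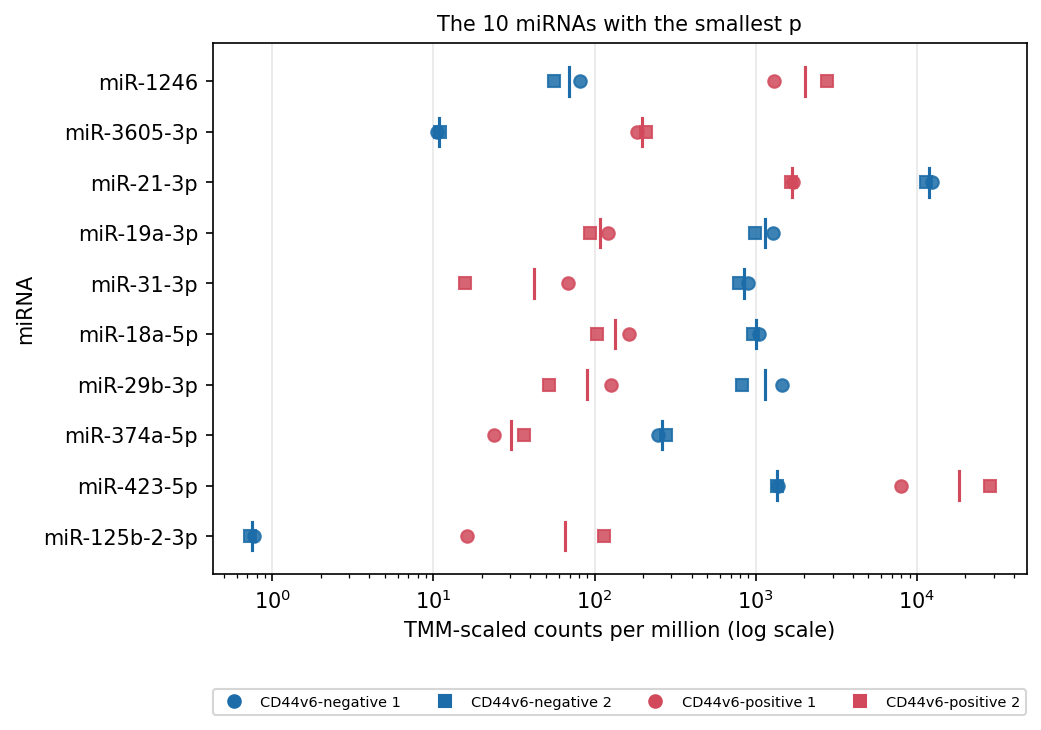
Level of the 10 miRNAs with the smallest p in each sample, in TMM-scaled CPM on a log axis. Circles and squares are samples 1 and 2 of each group and vertical bars are group means. In each miRNA the 2 groups do not overlap, which picking by small p favours. miR-1246 runs from 56.4 to 81.5 CPM in CD44v6-negative and from 1301 to 2757 CPM in CD44v6-positive samples.

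Their hairpins lie at scattered places of GRCh38. MIR1246 is on chromosome 2 (176600980 to 176601052, minus strand) outside any annotated gene of that strand, and MIR3605 on chromosome 1 (33332393 to 33332492, minus strand) in an exon of PHC2. MIR21 is on chromosome 17 (59841266 to 59841337, plus strand) in an exon of VMP1, and MIR423 on chromosome 17 (30117079 to 30117172, plus strand) in an exon of NSRP1. MIR18A (91350751 to 91350821) and MIR19A (91350891 to 91350972) lie on the plus strand of chromosome 13 in an exon of MIR17HG. MIR31 is on chromosome 9 (21512115 to 21512185, minus strand) in an intron of MIR31HG, MIR374A on chromosome X (74287286 to 74287357, minus strand) in an intron of FTX, and MIR125B2 on chromosome 21 (16590237 to 16590325, plus strand) in an intron of MIR99AHG. miR-29b-3p can come from MIR29B1 on chromosome 7 (130877459 to 130877539, minus strand) or MIR29B2 on chromosome 1 (207802443 to 207802523, minus strand).

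With edgeR, 0 miRNAs passed, the smallest adjusted p was 0.0787, and 27 miRNAs had an adjusted p under 0.1, of which 11 were higher and 16 lower in CD44v6-positive cells. At an unadjusted p under 0.05 there were 74 miRNAs higher and 100 lower, together 30.5% of those tested, against 28.5 miRNAs given by chance. DESeq2 called 52 miRNAs, 21 higher and 31 lower, and these included all 10 named above and 25 of the 27. limma-voom called 4, which were miR-1246, miR-3605-3p, miR-19a-3p and miR-21-3p. The 2 groups did not overlap in 339 miRNAs (59.5%, against 33.3% by chance for 2 against 2), 142 higher and 197 lower. That 33.3% holds for samples alike in depth, whereas both CD44v6-positive libraries were shallower, so it is no firm reference. Few or 0 reads can place a miRNA on the lower side. Of the tested miRNAs, 8 had 0 reads in both CD44v6-positive samples and 0 had none in both CD44v6-negative samples. The median log2 fold change over all tested miRNAs was -0.31 with TMM and moved by 0.34 with upper quartile and by 0.31 with total count scaling, and the higher share of the miRNAs at an unadjusted p under 0.05 moved from 42.5% to 58.4% and 56.6%. The number of calls was unstable, at 26, 43, 55 and 27 without CD44v6-negative sample 1, CD44v6-negative sample 2, CD44v6-positive sample 1 and CD44v6-positive sample 2.

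Among the 5 most abundant miRNAs, miR-92a-3p was at 142118 ± 3542 CPM in CD44v6-positive and 63211 ± 3842 CPM in CD44v6-negative cells, with a log2 fold change of 1.17 ± 0.39 (edgeR adjusted p = 0.125). miR-100-5p had a log2 fold change of -1.47 ± 0.72, and miR-21-5p, the guide strand of the miR-21 hairpin, of -1.53 ± 0.64. Both rested on single samples: without CD44v6-negative sample 1 they were -0.28 and -0.44, and without CD44v6-positive sample 1 they were -2.33 and -2.11. let-7a-5p (-0.45 ± 0.59) and miR-191-5p (-0.21 ± 0.44) differed by less than their standard errors, and both changed sign with total count scaling.

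Of the miRNAs known to target CD44, miR-34a-5p was at 545 ± 454 CPM in CD44v6-positive and 1263 ± 941 CPM in CD44v6-negative cells, a log2 fold change of -1.20 ± 0.84 (edgeR adjusted p = 0.378), and the groups overlapped. The value was -0.052 without CD44v6-negative sample 1 and -2.60 without CD44v6-positive sample 1. miR-373-3p had 2 reads and 1 read in the CD44v6-negative samples and 2 and 0 reads in the CD44v6-positive samples, at or under the floor of 3 reads. miR-520c-3p had 0 reads in every sample, which allows up to 0.381 CPM in the deepest and 19.4 CPM in the shallowest. Among the other miRNAs fixed for colorectal cancer, miR-145-5p (-1.22 ± 0.57) and miR-203a-3p (-1.36 ± 0.49) did not overlap between the groups, and with 1 sample left out miR-145-5p ran from -1.84 to -0.68. The groups overlapped for miR-143-3p (1.71 ± 0.88), miR-192-5p (0.80 ± 0.73), the hypoxia-induced miR-210-3p (-0.82 ± 0.86) and miR-221-3p (-0.01 ± 0.86). The first 2 of these turned negative without CD44v6-positive sample 2, at -0.02 and -0.43.

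The miR-17-92 cluster, a polycistron long studied as oncogenic, was lower as a list in CD44v6-positive cells. Its 12 tested members had a median log2 fold change of -2.19, against -0.31 over all tested miRNAs. Camera gave an adjusted p of 0.0266, but 0.818 with an estimated correlation. The members count both arms of a hairpin, and the preset correlation of 0.01 treats them as nearly independent. With edgeR none passed over all miRNAs tested, and 6 passed when adjusted over the list alone, 5 lower and 1 higher. DESeq2 called 5 members over all miRNAs, all lower (miR-17-5p, miR-18a-5p, miR-19a-3p, miR-19b-3p and miR-20a-5p), and limma-voom called miR-19a-3p. miR-20a-5p (-3.11 ± 0.91), miR-17-5p (-2.25 ± 0.71) and miR-19b-3p (-3.27 ± 0.63) were lower in both CD44v6-positive samples than in both CD44v6-negative samples. Without CD44v6-negative sample 1, miR-20a-5p was -1.72 and miR-17-5p -1.27, and without CD44v6-positive sample 1 they were -4.43 and -3.19. miR-92a-3p, the most abundant member, went the other way at 1.17 ± 0.39. Of the 12 tested members 3 had positive and 9 negative values, and the positive ones include miR-18a-3p (1.20 ± 0.60), from MIR18A on chromosome 13. Reads of miR-92a-3p and of the lower miR-19b-3p can also come from copies on chromosome X. The cluster's MIR17 lies on chromosome 13 (91350605 to 91350688, plus strand) and MIR92A1 at 91351314 to 91351391. The median GC content of the tested members was 42.7%, and after a correction for GC content, chosen after seeing the data, the list's median was -1.10 and its adjusted p 0.203. The list's adjusted p was 0.102 without CD44v6-negative sample 1, 0.117 without CD44v6-positive sample 2 and 0.0727 with the 10 CPM filter.

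**Figure D2:**
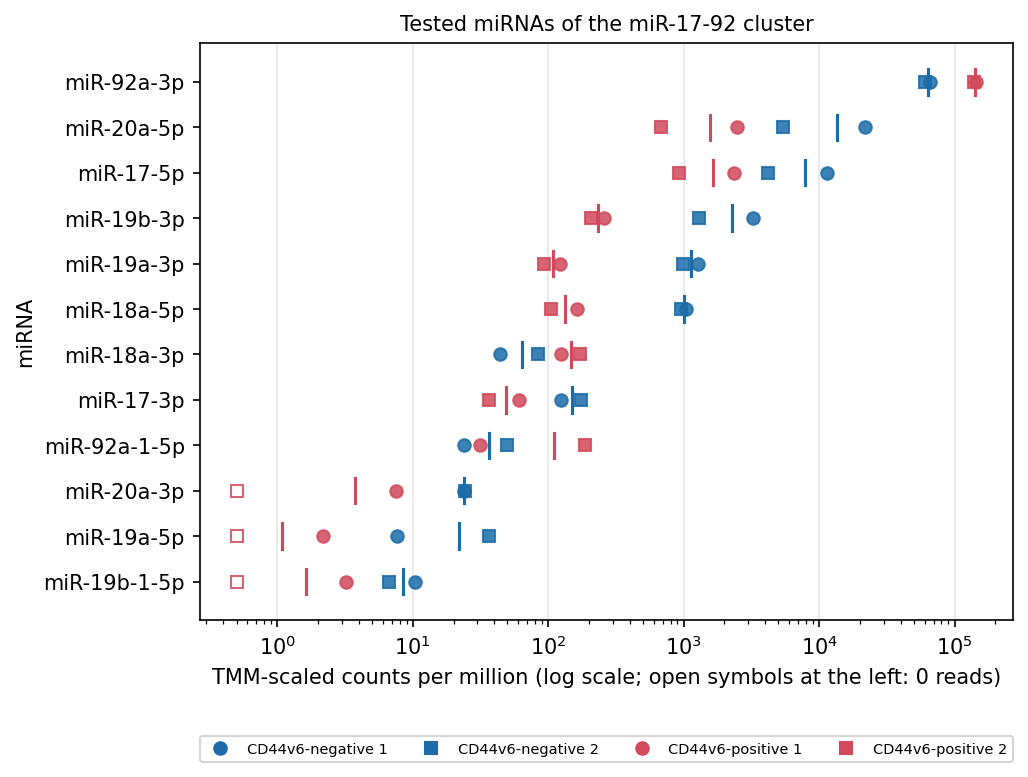
Level of each tested miR-17-92 member in each sample, in TMM-scaled CPM on a log axis, with open symbols at the left edge for samples with 0 reads. Vertical bars are group means. The guide strands miR-17-5p, miR-18a-5p, miR-19a-3p, miR-19b-3p and miR-20a-5p lie lower and miR-92a-3p higher in both CD44v6-positive samples, at 144622 and 139614 CPM against 65928 and 60494 CPM.

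The miR-29 family, known to repress collagen and DNA methyltransferase genes, was also lower as a list. All 6 tested members, which count both arms, had negative log2 fold changes. Their median was -1.54 (camera adjusted p = 0.0410, and adjusted p = 0.818 with an estimated correlation). With edgeR 0 passed over all miRNAs and 3 passed when adjusted over the list alone, and DESeq2 called miR-29b-3p over all miRNAs. The list's call was lost with the 10 CPM filter (adjusted p = 0.0727) and whichever sample was left out, with adjusted p of 0.205 and 0.169 without CD44v6-negative samples 1 and 2, and of 0.130 and 0.219 without CD44v6-positive samples 1 and 2. Beside miR-29b-3p, miR-29a-3p was at 3402 ± 1634 against 10632 ± 1191 CPM (-1.64 ± 0.51), miR-29c-3p had -1.21 ± 0.62 and miR-29b-1-5p -0.41 ± 0.54. With 1 sample left out miR-29a-3p ran from -2.36 to -1.003 and miR-29b-1-5p from -0.54 to -0.08. This was the list of lowest GC content among the 4 called, at a median of 37.5%, and with the GC correction its median was -0.47, its adjusted p was 0.572, and miR-29a-3p and miR-29b-1-5p had values of 0.04 and 1.03.

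Entries of miRNAs often reported raised in colorectal tumours, with both arms counted, were lower as a list in CD44v6-positive cells. The median log2 fold change was -1.53 over 12 tested members (camera adjusted p = 0.0266, and adjusted p = 0.818 with an estimated correlation). With edgeR none passed over all miRNAs and 2 passed when adjusted over the list alone, both lower. DESeq2 called miR-31-3p and miR-21-3p over all miRNAs, and limma-voom called miR-21-3p. These are the less abundant arms of their hairpins, so the calls do not cover miR-31-5p or miR-21-5p. The list also holds the members of the list of miR-183 with miR-96 and miR-182. miR-183-5p was at 3876 ± 979 against 11170 ± 1674 CPM (-1.53 ± 0.44), next to miR-21-5p above. The abundant miR-182-5p (-0.47 ± 0.42) and miR-31-5p (-0.37 ± 0.39) were closer between the groups, and with 1 sample left out they ran from -0.54 to -0.12 and from -0.46 to -0.18. The list's adjusted p was 0.196 without CD44v6-negative sample 1, 0.149 without CD44v6-positive sample 2 and 0.0582 with the 10 CPM filter. The median GC content of the list was 49.5%, and with the GC correction its median was -1.01 and its adjusted p 0.0188.

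Entries thought to derive from other noncoding RNA were higher as a list in CD44v6-positive cells. The list was fixed from general knowledge and not from positions or sequences, and the hairpins of miR-1246, miR-1260a, miR-1260b and miR-4454 overlap no annotated gene of their strand. The median log2 fold change over 9 tested members was 1.19 (camera adjusted p = 0.010, and adjusted p = 0.818 with an estimated correlation). With edgeR 0 passed over all miRNAs, and 4 passed when adjusted over the list alone, all higher. DESeq2 called miR-1246 and miR-4454 over all miRNAs, and limma-voom called miR-1246. miR-1246, reported to match a part of the spliceosomal U2 RNA, led the list. miR-1260a (1.19 ± 0.48), miR-1260b (0.96 ± 0.51) and miR-3607-3p (2.57 ± 0.81) were higher in both CD44v6-positive samples than in both CD44v6-negative samples. Without CD44v6-positive sample 1, miR-1260a was 0.74, miR-1260b 0.39 and miR-3607-3p 1.65. The median GC content of the list was 48.6%, and with the GC correction its median was 2.00 and its adjusted p 0.00019. Without CD44v6-positive sample 1 the list's adjusted p was 0.110, and with the 10 CPM filter this was the only list still called.

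With fry, which asks whether a list moves one way on balance, none of these 4 lists passed, with adjusted p of 0.104 for miR-17-92 and miR-29 and of 0.169 for the other lists. With fry's mixed test, which asks whether members change in either direction, the noncoding RNA list and miR-34 with miR-449 had an adjusted p of 0.0186, and the let-7 and miR-200 families of 0.0422.

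The miR-200 family, which maintains the epithelial state by repressing ZEB1 and ZEB2, missed the threshold for lists at a camera adjusted p of 0.0728, with an adjusted p of 0.818 with an estimated correlation and of 0.130 with fry. Its 9 tested members had a median log2 fold change of -1.11, and with edgeR 0 passed over all miRNAs and 4 when adjusted over the list alone, all lower. DESeq2 called 4 members over all miRNAs, all lower, among them miR-141-3p and miR-200a-3p. The list was called with no filter, with the replicate number as a block and after the GC correction. miR-141-3p was at 1556 ± 543 against 8278 ± 4146 CPM (-2.41 ± 0.57), and miR-200a-3p at 442 ± 175.8 against 1726 ± 574 CPM (-1.96 ± 0.55). miR-200b-3p (-0.23 ± 0.42) and miR-200c-3p (-0.61 ± 0.69), which derive from the same transcripts as those 2, overlapped between the groups, and miR-200b-3p turned positive with upper quartile and total count scaling.

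The let-7 family, associated with differentiation, had a median log2 fold change of -0.45 over 19 tested members, close to that of all miRNAs (camera adjusted p = 0.464). With edgeR 0 members passed, and DESeq2 called 1, which was lower. With no filter the list was called. let-7f-5p (-0.36 ± 0.45), let-7g-5p (-0.58 ± 0.62) and let-7b-5p (0.61 ± 0.58) overlapped between the groups, as did let-7a-5p. let-7b-5p ran from 0.16 to 1.51 with 1 sample left out, and the list's median was 0.12 after the GC correction. The list of miR-34 and miR-449 had a median of -0.45 over 6 tested members (camera adjusted p = 0.558), with 0.09 after the GC correction. With edgeR 0 members passed over all miRNAs and 1 when adjusted over the list alone, the passenger strand miR-34a-3p, which was lower at 1.08 ± 1.53 against 26.1 ± 6.12 CPM (-3.92 ± 0.98, edgeR adjusted p over all miRNAs = 0.110). It had 114 and 168 reads in the CD44v6-negative samples and 2 and 0 reads in the CD44v6-positive samples, so its size is poorly known. Leaving out 1 sample, it ran from -9.58, where the CD44v6-positive sample kept has 0 reads, to -3.34. Neither DESeq2 with default filtering nor limma-voom called a member, and miR-34a-3p passed over all miRNAs with no filter, with the replicate block and with DESeq2 tuned to 0.05. Beside miR-34a-5p, miR-449c-5p (-0.43 ± 0.64), miR-449a (-0.47 ± 0.60) and miR-449b-5p (0.15 ± 0.77) were read at under 100 CPM in each sample, and with 1 sample left out miR-449a ran from -0.48 to -0.29.

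No other list passed. Lower medians were seen for the miR-106a-363 cluster (-2.50, 3 tested), miR-424 with miR-503 (-1.68, 6 tested), miR-183 with miR-96 and miR-182 (-1.53, 5 tested) and miR-23 with miR-24 and miR-27 (-1.11, 10 tested), each with a camera adjusted p of 0.237. In that order, these medians were -1.74, -0.62, -1.01 and -0.81 after the GC correction. With no filter miR-183 with miR-96 and miR-182, miR-23 with miR-24 and miR-27, and miR-15 with miR-16 were called. HOX-cluster miRNAs had a median of -1.17 (9 tested, adjusted p = 0.464), miR-181 of -0.56 (8 tested, 0.733), miR-30 of -0.50 (9 tested, 0.323), miR-15 with miR-16 of -0.44 (10 tested, 0.480) and miR-106b-25 of -0.19 (6 tested, 0.752), the last of which was 0.14 with upper quartile scaling. After the GC correction these medians were -0.52, -0.17, -0.12, -0.03 and -0.60, in that order. The imprinted DLK1-DIO3 cluster had 11 tested members of 91, a median of -0.44, a mean of -0.17 and a camera adjusted p of 0.951 in the higher direction, and its median was 0.26 after the GC correction. Medians above 0 were seen for the intestinal miR-192, miR-194 and miR-215 (0.80, 3 tested, 0.464), NF-kB-responsive miRNAs (0.77, 4 tested, 0.542), miR-221 with miR-222 (0.06, 4 tested, 0.733) and miR-99, miR-100 and miR-125 (0.04, 10 tested, 0.918). miR-210 had 2 tested arms, too few for a list test, with values of -0.82 and 1.22. Of the pluripotency clusters (11 entries) and the chromosome 19 cluster (35 entries), 0 members had enough reads to be tested.

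Markers of other cell types did not pass as lists. Those of blood and endothelium had a median of 0.63 over 8 tested members (camera adjusted p = 0.733), with miR-486-5p at 0.67 ± 0.54, miR-126-5p at -1.52 ± 0.48, miR-126-3p at -0.94 ± 0.51 and miR-142-5p at 0.68 ± 0.79. The red-cell miRNA miR-451a had the largest change of this list, at 15.1 and 281 CPM in the CD44v6-positive samples against 24.9 and 7.62 CPM in the CD44v6-negative samples (3.12 ± 1.35), and its log2 fold change was 0.08 without CD44v6-positive sample 2. miR-486-5p ran from 0.37 to 1.47 and miR-126-3p from -1.22 to -0.59 with 1 sample left out. Those of stroma and muscle had a median of 0.25 over 6 tested members (adjusted p = 0.767). Those of neural cells and liver had a median of 0.41 over 6 tested members (adjusted p = 0.752), and with edgeR 1 passed when adjusted over the list alone. That was the liver miRNA miR-122-5p, at 48.6 and 610 CPM in the CD44v6-positive samples against 4.59 and 3.99 CPM in the CD44v6-negative samples (6.22 ± 1.32, edgeR adjusted p = 0.0787). DESeq2 called it, and its log2 fold change was 3.71 without CD44v6-positive sample 2. The other named members were miR-9-5p (-1.19 ± 0.60), miR-9-3p (-2.05 ± 0.69) and miR-138-5p (0.24 ± 0.74). miR-9-5p ran from -1.85 to -0.49 and miR-138-5p from 0.06 to 0.69 with 1 sample left out.

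Log2 fold change rose with GC content across the 569 tested miRNAs with a value (Spearman rho = 0.42, bootstrap 95% interval 0.35 to 0.49), which are not independent replicates. In 4 equal bins from lowest to highest GC content, median log2 fold changes were -1.21, -0.45, -0.07 and 0.70. The relation was chosen for testing after the fold changes were seen.

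**Figure D3:**
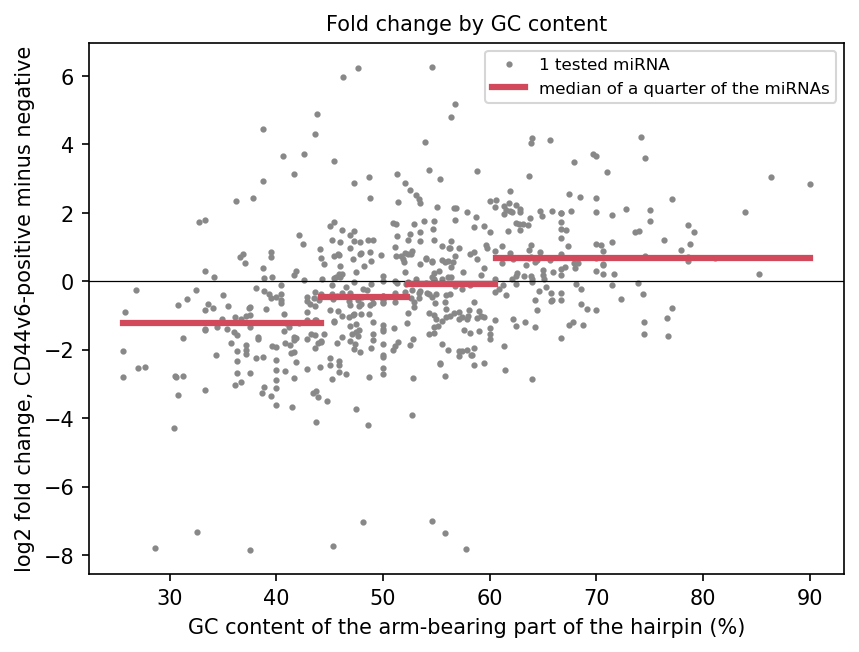
Log2 fold change, CD44v6-positive minus CD44v6-negative, against the GC content in percent of the hairpin part that carries the arm. Each point is 1 of 569 tested miRNAs and red bars are medians of 4 equal bins by GC content, which run from -1.21 to 0.70. Of the tested miRNAs, 8 with 0 reads in both CD44v6-positive samples have fitted values of -7.01 or lower, which are no bound on the true change.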

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

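The count of 0 edgeR calls and the 10 miRNAs of smallest p behaved differently across settings. Each of the 10 kept its direction in every alternative that tested it (18 or 19) and passed 0.05 in 8 to 11 of them. The count of calls stayed at 0 with RLE, upper quartile, the most abundant miRNA left out, the 10 CPM filter, robust and both legacy fits, the GC correction and the 2-fold minimum. It was 48 with total count scaling, 77 with no filter, 52 with DESeq2, 4 with limma-voom and 26 to 55 with 1 sample left out. In alternatives chosen after seeing the data it was 73 with DESeq2 tuned to 0.05 and a median of 23.5 after thinning. In the total count, no filter and leave-one-out fits edgeR estimated infinite prior degrees of freedom, so 1 spread was shared by all miRNAs, against 4.31 in the reported fit. Each leave-one-out fit has 1 group of a single sample, assumed to vary like the other. The count at an unadjusted p under 0.05 was 76 after thinning, where fewer miRNAs were tested, and 94 to 166 with 1 sample left out. Lists called were 9 with no filter (adding let-7, miR-200, miR-15 with miR-16, miR-23 with miR-24 and miR-27, and miR-183 with miR-96 and miR-182), 1 with the 10 CPM filter (that of noncoding RNA), 0 with an estimated correlation, 0 with fry and 1 to 3 with 1 sample left out. Replicate numbers are shared by the groups, and deviations of same-numbered samples correlated at 0.37. The fitted common spread (edgeR's common dispersion) was 0.270 without and 0.115 with the number as a block. With only 2 pairs this does not show that the numbers pair samples, since sample 2 is also the shallower in each group. With the number as a block there were 228 calls, 269 miRNAs at an unadjusted p under 0.05 and 5 lists, among them the miR-200 family, again with an infinite prior. Among values of single named miRNAs, 51 reversed, 944 kept direction and side, and the others kept direction and passed. The cause of the reversals was not tested. With 1 sample left out, the log2 fold change of 41 of 64 named miRNAs moved by over 1.5 times or changed sign, and none of the 10 of smallest p was among them. Those 10 were picked by small p in these same samples, which favours groups that do not overlap and values that hold across refits. That they held is therefore no independent support. With RLE miR-221-3p was 0.064, and with upper quartile miR-191-5p was 0.12, miR-200b-3p 0.10 and miR-221-3p 0.35. With total count let-7a-5p was 0.0079, miR-191-5p 0.087, let-7f-5p 0.032, miR-200b-3p 0.031 and miR-221-3p 0.38. With no filter miR-449b-5p was -0.25 and miR-138-5p -0.16, with the 10 CPM filter miR-191-5p was 0.0050 and miR-221-3p 0.18, and with DESeq2 at either filtering miR-449b-5p was -0.019. With the GC correction let-7a-5p was 0.30, let-7f-5p 0.74, let-7g-5p 0.23, miR-449a 0.36, miR-29a-3p 0.044, miR-29b-1-5p 1.03, miR-138-5p -0.092 and miR-221-3p 0.52. After thinning let-7a-5p was 0.077, miR-191-5p 0.27, let-7f-5p 0.17, miR-200b-3p 0.25, miR-29b-1-5p 0.047, miR-182-5p 0.063, miR-31-5p 0.14 and miR-221-3p 0.44. With 1 sample left out values that changed sign ran as follows: let-7a-5p from -0.89 to 0.57, miR-191-5p from -0.67 to 0.28, let-7f-5p from -0.54 to 0.17, let-7g-5p from -1.44 to 0.22, miR-200c-3p from -1.81 to 0.19, miR-449b-5p from -0.21 to 0.71, miR-210-3p from -2.21 to 0.46, miR-221-3p from -1.70 to 1.06, miR-449c-5p from -0.70 to 0.21, miR-200b-3p from -0.57 to 0.18, miR-142-5p from -0.55 to 1.31, miR-143-3p from -0.025 to 2.39 and miR-192-5p from -0.43 to 1.39. Fits on the 8 sequencing entries, with or without the sequencing set, and on each set alone were not run, since the columns join the entries.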

Other observations

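The tests on miR-1246 and on miR-122-5p, the count of miRNAs high in 1 sample alone, the miRNAs in the next 2 paragraphs, miR-34a-3p, miR-451a, miR-215-5p and miR-30a-5p were chosen only after the values were seen. The tests on GC content, depth and other splits were written down after the fold changes but before the values they measure.

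Arms of 1 hairpin moved together in part (rho = 0.45), with 41 of 137 hairpins at opposite signs. Of 47 hairpins with both arms at a mean of at least 50 CPM, 17 had opposite signs, 14 with upper quartile and 15 with total count scaling, and in 6 both arms lay over 1 SE from 0. The difference between the 2 samples of a group gave opposite signs in 21 (CD44v6-negative) and 14 (CD44v6-positive) of the 47. Such differences hold no change between groups, so their signs may be near random, and the comparison does not decide whether 17 is many. The count with both arms over 1 SE from 0 was not taken within groups. For MIR18A, miR-18a-5p was at -2.88 ± 0.53 and miR-18a-3p at 1.20 ± 0.60 (0.88 to 1.91 with 1 sample left out). For MIR106B, in an intron of MCM7, miR-106b-5p was at 167 ± 7.15 against 902 ± 17.1 CPM (-2.44 ± 0.49) and miR-106b-3p at 438 ± 22.7 against 313 ± 53.8 CPM (0.48 ± 0.48, and 0.30 to 0.84 with 1 sample left out). For MIR1307, miR-1307-5p was at -2.39 ± 0.79 and miR-1307-3p at 0.65 ± 0.57, but without CD44v6-negative sample 2 miR-1307-5p was at -0.81, and with 1 sample left out miR-1307-3p ran from 0.35 to 1.33. For MIR31, miR-31-3p was at 41.8 ± 37.0 against 841 ± 79.7 CPM while miR-31-5p was at 13322 ± 440 against 17204 ± 332 CPM.

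Among abundant miRNAs outside the fixed lists, miR-92b-3p, which shares its seed with miR-92a-3p, was at 64675 ± 15313 CPM in CD44v6-positive against 15130 ± 5321 CPM in CD44v6-negative cells (2.10 ± 0.48, edgeR adjusted p = 0.0908). miR-423-3p was at 1.47 ± 0.43, in the direction of miR-423-5p from the same hairpin. Neither passed in edgeR's reported fit. miR-92b-3p passed with total count scaling, with the replicate block, after thinning, with DESeq2 tuned to 0.05, and without CD44v6-negative sample 2 or CD44v6-positive sample 1. miR-423-3p passed with total count scaling, with the block and after thinning.

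Fold change rose with GC content (rho 0.42), and the relation was present among the miRNAs above and below the median abundance (0.38 and 0.45). Unequal read depth is argued against, since with all 4 samples thinned to 154481 reads the median rho over 20 draws was 0.355 (0.321 to 0.378). Transcription of each miRNA gene alone stays open. The difference between arms of 1 hairpin followed their difference in GC content (rho = 0.270, bootstrap 95% interval 0.103 to 0.43, 137 hairpins). That interval lies only just above the bound of 0.1 set beforehand, and it covers the spread over hairpins and not over samples. The same relation was not measured between samples of 1 group, and some of these arms had 0 reads in both CD44v6-positive samples. This does not decide, and the arms also moved together (rho = 0.45). Poorer recovery of AU-rich small RNAs from libraries of low yield remains open: within CD44v6-positive cells the shallower minus the deeper sample had a rho of 0.0487 (-0.034 to 0.13), and within CD44v6-negative cells 0.13 (0.037 to 0.21). Among miRNAs above the median abundance these were -0.025 (-0.14 to 0.091) and 0.17 (0.047 to 0.28). The intervals overlap, each value rests on 1 pair of samples, and whether the groups differ was not tested. The shallow libraries are all CD44v6-positive. A difference in arm choice or stability between the sorted cells may give the same pattern and was not tested.

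The 74 higher and 100 lower miRNAs at an unadjusted p under 0.05 stood against 14 and 4 miRNAs for the other 2 splits of the 4 samples, so 1 of 3 splits gave as many, too few splits for a share under 0.05. Unequal depth is argued against as the whole cause, since after thinning the median count was 76 (62 to 84) of a median of 229.5 tested, over 10% in every draw. A biological difference between the sorted cells and a technical difference between deep and shallow libraries, which may differ in RNA input, cannot be told apart here, because each group holds 1 kind of library.

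Whether the higher level of miR-1246 reflects RNA breakdown fragments stays open. The other 8 tested members of the noncoding RNA list had a median log2 fold change of 1.08 (bootstrap 95% interval -0.26 to 2.57), which holds 0 and does not decide. The members did not move alike, and miR-4454, at 31 reads and 1 read in the CD44v6-positive samples, rests on few reads. Regulation of miR-1246 itself was not tested and stays open. miR-122-5p, also abundant in serum, may have been carried over with serum RNA, while the samples are of a cell line, which holds no blood cells. The blood and endothelial list had a median of 0.627 (-0.94 to 1.65), and its most abundant members miR-486-5p and miR-126-5p went opposite ways. Those members had means of 2132 and 3138 CPM in CD44v6-negative cells themselves, so the list says little on carry-over and does not decide. CD44v6-positive sample 2, which held most of miR-122-5p, stood apart: 14 tested miRNAs were at 100 CPM or more in it and at least 4 times every other sample, against 2 for CD44v6-positive sample 1 and 1 and 0 for CD44v6-negative samples 2 and 1. Beside miR-122-5p they include miR-451a, miR-143-3p (4972 against 746 CPM in CD44v6-positive sample 1), miR-30a-5p (448 against 64.7 CPM) and miR-215-5p (250 against 59.3 CPM). They also include miR-125b-2-3p (115 against 16.2 CPM), which is among the 10 miRNAs of smallest p. The 14 are not named in full, so these names do not show which kind of miRNA was high. miR-192-5p (4560 against 1032 CPM) was high in CD44v6-positive sample 2 too. miR-486-5p and miR-126-5p were not higher in CD44v6-positive sample 2 than in CD44v6-positive sample 1. CD44v6-positive sample 2 is the shallowest library, and what sets it apart was not tested. The cells were sorted from serum-free culture, per the labels' protocols.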
